A study of Rattus norvegicus with 12 samples.

How the data were processed

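The data are gene-level RNA-seq tables of 12 libraries of rat heart cells: neonatal cardiomyocytes and neonatal cardiac fibroblasts, each cultured with WT or St8sia1-KO mouse mast cells, 3 libraries per group. Per the labels' protocols, cells that did not adhere were washed off with buffer after the co-culture, and total RNA of the adherent cells was extracted with RNAiso Plus, purified on RNeasy columns with DNase digestion and made into libraries with a NEBNext Ultra RNA kit. The extraction text also names mouse ventricular tissue, which is in no group analysed here; titles and source fields were followed. The number of mast cells per well differs between the labels' protocol and the treatment field and is not given here. The treatment field of KO replicates 2 and 3 in both cell types names St8sia2 and St8sia3, where the titles and the series design name St8sia1; libraries were grouped by title, and a fit without these libraries was run. Chromatin accessibility and histone variant profiles of mast cells, which the design also mentions, are not analysed here.

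The deposited values are whole-number estimated counts per gene (expected counts), 1 table per cell type. The submitters' processing notes name fastp 0.18.0, HISAT2 2.4 and RSEM 1.3.3 among the tools, and rat builds rn6 and Rnor_6.0 beside mouse builds, without saying which step or table each belongs to. The tables name no build, and the names of their unplaced contigs look like those of a later rat assembly than Rnor_6.0, so the build of the coordinates is uncertain. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes cannot be told apart. Reads of remaining mouse mast cells may be counted on rat genes where the sequences are alike, which was not tested. The values were rounded to whole numbers, which changed none of them, and every entry carried an Ensembl identifier.

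How many deposited counts stand for an independent fragment is not known. Values of 4 occurred 2139 times in NRCM and 2066 times in CF, more often than values of 1 (1938 and 1829), 2 (1728 and 1711), 3 (1852 and 1688) or 5 (1331 and 1211). Between libraries of a group, squared differences at 10 to 30 counts were 3.27 to 4.3 times counting noise in NRCM and 3.17 to 3.38 times in CF, where independent counts give 1; these ratios include the variation between cultures. Totals can therefore overstate depth, and floors and intervals from counts cover counting error only. edgeR's quasi-likelihood dispersion is estimated from the libraries and can take up such an excess. Whether it does so for each gene with few counts was not tested. No pair of libraries agreed within counting noise: among the genes with the highest counts the ratio was at least 20.6.

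The deposited values covered 30512 entries in NRCM and 30508 in CF. In NRCM 452 identifiers occurred on several entries (988 in all) and in CF 462 (1008 in all); these were summed, leaving 29976 and 29962 genes. Gene symbols are those of the tables. List members absent under their symbol were matched through the NCBI gene identifier or a single RefSeq synonym, using a RefSeq gene table of another assembly for names only. Members without a match, such as Pln, Timp2, Isg15, Cd36 and Mcpt4, are not analysed here.

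Tests were run in R 4.3.3. For each cell type alone, genes passing filterByExpr were scaled by TMM factors and tested with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest, KO minus WT, no block), with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. The difference of effects, CF minus NRCM, was tested as an interaction over all 4 groups. The 25 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. All tests are two-sided.

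Genes were named by a rule fixed before the data were examined: genes past the threshold with a symbol, at least 10 CPM in the higher group and all 3 KO libraries on the same side of all 3 WT libraries, up to 10 per direction; where none passed in a direction, the 5 of that kind with the smallest p; up to 3 members of each list with the smallest p, of which the text prints a part; and a fixed set of cardiac and fibroblast genes. For the difference of effects, 5 genes per direction with a symbol and 10 CPM were taken by p, since none passed. Other named genes were chosen after their values were seen.

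Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE scaling, library size alone, no filter, a filter of 1 CPM in 3 libraries, a replicate block, all 4 groups in a single fit, a test against a fold of 1.2, each library left out in turn, and, for lists, an estimated correlation, fry and ranks. Added after seeing the data were counts divided by 4, entries with a shared identifier kept apart, RLE scaling for lists and the test of lists on the difference of effects.

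The gene tests were checked on a single simulated data set per comparison, with 50 changed genes per fold size. In the NRCM comparison (17550 genes tested), 4% of genes changed 1.25-fold, 64% of those changed 1.5-fold and 88% of those changed 2-fold were recovered, with 8 false calls. In the CF comparison (17373 genes tested) the shares were 54%, 82% and 98%, with 22 false calls. For the difference of effects (18210 genes tested) they were 4%, 46% and 90%, with 9 false calls. Of genes changed 3-fold, 98% were recovered in NRCM, 100% in CF and 96% for the difference. In each comparison the false calls were a larger share of all calls than the threshold of 0.05, most so in CF. A single simulated data set does not measure the rate of false calls. The CF gene calls may still hold more false ones than the threshold states. Camera recovered a list shifted 1.1-fold in 10 of 10 simulated NRCM data sets (17779 genes) and made 0 false list calls; simulated genes vary independently, which real genes do not.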

Results

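RNA was sequenced from 2 kinds of primary rat heart cell, neonatal cardiomyocytes (NRCM) and neonatal cardiac fibroblasts (CF), that had been cultured for 48 h together with mouse bone marrow-derived mast cells. The mast cells were either wild type (WT) or lacked St8sia1 (KO), the sialyltransferase that makes the ganglioside GD3. Each of the 4 groups, NRCM with WT, NRCM with KO, CF with WT and CF with KO mast cells, had 3 libraries, described as biological replicates. The libraries held between 131.9 M and 166.9 M counts in NRCM and between 150.2 M and 212.6 M in CF. No group without mast cells was analysed here, so every comparison sets KO against WT mast cells. The knockout is in the mouse cells, and the tables hold rat genes, so the rat St8sia1 count does not check the genotype. St8sia1 stood at 0.433 ± 0.189 CPM (counts scaled to library size; SD, n = 3) in NRCM with WT and 0.423 ± 0.0621 CPM with KO mast cells, and at 0.179 ± 0.0346 and 0.19 ± 0.0355 CPM in CF.

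The cardiac cell types differed in their marker levels as follows. Myh6, the alpha myosin heavy chain of cardiac muscle, averaged 12100 CPM in NRCM with WT mast cells and 2373 CPM in CF with WT mast cells. The atrial natriuretic peptide gene Nppa averaged 24080 and 3886 CPM. Postn, a matrix protein of activated fibroblasts, averaged 221.8 CPM in NRCM and 4661 CPM in CF. The fibroblast receptor gene Pdgfra averaged 30.1 and 1512 CPM. Other markers were less separated: the cardiac muscle genes Tnnt2 and Actc1 averaged 3743 and 7180 CPM in NRCM and 1284 and 2286 CPM in CF. The collagen gene Col1a1 averaged 3775 CPM in NRCM and 8742 CPM in CF. Cardiomyocyte and fibroblast transcripts were thus present in both kinds of culture. The CF libraries also held transcripts of macrophage genes, with Lyz2 at 422.9 ± 22.5 CPM and Cd68 at 57.1 ± 2.94 CPM with WT mast cells (SD, n = 3), against 19.8 ± 0.958 and 9.09 ± 0.839 CPM in NRCM. Of the mast cell genes, Fcer1a and Ms4a2, which encode chains of the high-affinity IgE receptor, had 0 counts in all 12 libraries. This allows up to 0.0227 CPM in the shallowest of them (3 counts, counting error only). Mouse transcripts are bounded by it only where their reads match rat genes.

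The first comparison asked which cardiomyocyte genes differed after culture with KO rather than WT mast cells. The inflammatory cytokine and NF-kB target list fell: 32 of its 33 members had a lower mean in NRCM cultured with KO mast cells, with a median log2 fold change of -0.16 (0.897-fold), and camera gave an adjusted p of 4.93e-09. With an estimated correlation between genes the camera adjusted p = 0.0465, the largest over its 14 alternatives (from 3.51e-10). The granulocyte colony-stimulating factor gene Csf3 went from 15.9 ± 0.71 CPM with WT to 10.4 ± 2.29 CPM with KO mast cells (SD, n = 3), a log2 fold change of -0.62 ± 0.15 (SE). Nos2, the inducible nitric oxide synthase, stood at 92.5 ± 1.01 and 76.1 ± 6.95 CPM (-0.28 ± 0.071). Lcn2, the secreted iron-carrier binding protein lipocalin 2, was at 1886 ± 91 and 1534 ± 105 CPM (-0.30 ± 0.076). These 3 genes passed at 0.05 adjusted over the list alone, all 3 of them lower, and 0 members passed over all genes tested. Il1b and Cxcl3 had log2 fold changes of -0.31 ± 0.1 and -0.33 ± 0.11. The call held in each of the 6 fits that left out a library.

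Lists of metabolic genes had median folds of up to 1.08 in NRCM with KO mast cells. The glycolysis and hypoxia list had 27 of 29 members above 0, a median log2 fold change of 0.11 and a camera adjusted p of 3.39e-05. The cholesterol synthesis list had 19 of 25 members above 0, a median of 0.11 and an adjusted p of 5.46e-05. Neither call held with an estimated correlation, where the camera adjusted p = 0.386 and adjusted p = 0.191 in that order (over all alternatives, 2.48e-06 to 0.665 and 1.01e-05 to 0.273). The glycolysis median was 0.064 without KO replicate 2 and 0.17 without KO replicate 3. Egln1, an oxygen-sensing prolyl hydroxylase, was at 112.9 ± 5.76 CPM with WT and 130.1 ± 18.2 CPM with KO mast cells (SD, n = 3), and its log2 fold change of 0.20 ± 0.098 (SE) was 0.085 without KO replicate 2. Hk2, hexokinase 2, had a log2 fold change of 0.31 ± 0.16, with KO replicate 2 at 419.6 CPM and the other KO libraries at 271.2 and 272.7 CPM. In the cholesterol list, Msmo1, a sterol demethylating enzyme, was at 23.8 ± 1.29 and 28.1 ± 0.597 CPM, and Hmgcs1, an early enzyme of the pathway, at 59.1 ± 2.9 and 65.7 ± 0.935 CPM. In either list 0 members passed adjusted over the list alone, and 0 over all genes tested. Oxidative phosphorylation genes (30 of 35 above 0, median 0.058, camera adjusted p = 0.018) and extracellular matrix genes (27 of 33 above 0, median 0.071, adjusted p = 0.029) were also called higher, with adjusted p = 0.903 and adjusted p = 0.904 under an estimated correlation (over all alternatives, 3.14e-05 to 0.967 and 0.00148 to 0.967). The estimated correlations of these lists were 0.598 and 0.656 in that order, against the preset 0.01, so the p from the preset is too small. Both calls were lost when any of several libraries was left out, and both were lost with a block for replicate number. The oxidative phosphorylation call was lost in 4 of the 6 fits that left out a library, with an adjusted p of 0.0755 without WT replicate 1, 0.242 without WT replicate 3, 0.633 without KO replicate 2 (median 0.0066) and 0.184 without KO replicate 3; the median was 0.089 without KO replicate 1. The matrix call was lost without WT replicate 2 (median 0.038, adjusted p = 0.64), without WT replicate 3 (0.104) and without KO replicate 2, where the median turned to -0.024 (adjusted p = 0.226), and its median was 0.11 without WT replicate 1. KO replicate 2 stood apart from the other 5 NRCM libraries: mitochondrial rRNA took 1.96% of its counts against 0.862% to 0.96% in the others. Without it, camera called 13 lists in place of 6.

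Mast cell markers formed the sixth list called in NRCM, with 10 of 11 tested members above 0, a median log2 fold change of 0.14 and a camera adjusted p of 9.59e-04 (adjusted p = 0.191 with an estimated correlation; adjusted p = 0.0599 without KO replicate 1; over all alternatives, 5.08e-04 to 0.291). The median was 0.055 without WT replicate 2, 0.075 without KO replicate 1, 0.064 without KO replicate 2 and 0.2 without KO replicate 3. Cma1, a chymase of mast cell granules, averaged 2.36 ± 0.294 CPM with WT and 5.1 ± 0.955 CPM with KO mast cells, a log2 fold change of 1.11 ± 0.16 (SE). Cpa3, the mast cell carboxypeptidase A3, averaged 1.61 ± 0.177 and 2.72 ± 0.206 CPM, a log2 fold change of 0.76 ± 0.13. These 2 genes passed adjusted over the list alone, and 0 passed over all genes tested in edgeR (adjusted p = 0.632 for Cma1). Kit, the stem cell factor receptor, stood at 42.6 ± 1.08 and 43.3 ± 1.79 CPM.

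Across all 17779 genes tested in NRCM, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 444 genes, 180 higher and 264 lower, where chance alone gives 889. DESeq2 called 14 genes, 5 higher and 9 lower, Cma1, Cpa3, Mmp9, Mybl1, Atrx and Serpinb2 among them, and limma-voom called 3. A single edgeR fit of all 4 groups called 3, and leaving out KO replicate 2 gave 1, Cd28. In every NRCM library with KO mast cells, Mybl1, a transcription factor of the Myb family, and Atrx, a chromatin remodeller, were above every library with WT mast cells, with log2 fold changes of 0.31 ± 0.064 and 0.26 ± 0.054 (SE); neither passed. The same held for Dmd, which encodes dystrophin (0.32 ± 0.082) and the helicase-like factor Hltf (0.20 ± 0.054). On the lower side, the gelatinase gene Mmp9 went from 110.4 ± 2.7 to 87.8 ± 5.68 CPM (SD, n = 3), with a log2 fold change of -0.33 ± 0.062, the plasminogen activator inhibitor gene Serpinb2 had -0.50 ± 0.11 and the secreted phospholipase gene Pla2g2a -0.31 ± 0.074. The cardiac genes Nppa, Nppb, Myh6, Myh7, Acta1 and Atp2a2 differed by less than 2 SE: Nppa had a log2 fold change of 0.0079 ± 0.087, Nppb -0.067 ± 0.076, Myh6 0.13 ± 0.083, Myh7 0.1 ± 0.12, Acta1 0.12 ± 0.17 and the calcium pump gene Atp2a2 0.13 ± 0.13. Ttn, which encodes titin, had 0.20 ± 0.097, and the connexin gene Gja5 -0.28 ± 0.1; neither passed over its list alone or over all genes.

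The other 19 lists were not called in NRCM by camera. Among lists of heart muscle function, sarcomere genes had a median log2 fold change of 0.051 (adjusted p = 0.123), fetal and hypertrophic genes 0.058 (0.342), calcium handling genes 0.058 (0.21) and fatty acid oxidation genes 0.069 (0.429), where camera's adjusted p stands in brackets. Matrix proteases and inhibitors had 13 of 21 members below 0 and a median of -0.039 (0.0908); Mmp9 passed adjusted over the list alone. The median was 0.0064 for myofibroblast and TGF-beta genes (0.853), -0.034 for the interferon response (0.826), -0.015 for the cell cycle (0.841), 0.051 for the unfolded protein response (0.153) and -0.0042 for immediate early genes (0.545). It was 0.06 for p53 targets (0.244), 0.031 for NRF2 and oxidative stress genes (0.995) and -0.039 for ganglioside metabolism (0.478). For other cell types it was -0.0028 for macrophage markers (camera's direction up, 0.794), -0.015 for endothelial (0.503), 0.025 for mural (camera's direction down, 0.794), -0.053 for epicardial (0.123), 0.0072 for fibroblast identity (camera's direction down, 0.841) and 0.015 for erythroid markers (0.933). Several of these depended on KO replicate 2. Without it, cell cycle genes had a median of 0.14 (adjusted p = 2.18e-06) and interferon response genes 0.074 (adjusted p = 2.21e-04), both in the opposite direction. The NRCM list sarcomere and contraction (0.00209) and the immediate early list (2.17e-04) passed. Fatty acid oxidation (median -0.037, 0.0444) and NRF2 genes (-0.04, 0.0222) passed in the opposite direction. Also past the threshold were matrix protease (0.0461), epicardial (0.0443) and fibroblast identity genes (-0.051, 0.0473), the last with its median on the other side of 0. Without WT replicate 1, sarcomere (6e-04), fetal (0.0178), calcium handling (0.041) and unfolded protein response genes (0.0205) passed. Without KO replicate 1 the cell cycle (0.00376) and fatty acid oxidation (0.0304) lists passed.

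The second comparison asked the same of cardiac fibroblasts. In CF, edgeR called 7 of 17547 genes at an adjusted p under 0.05, 6 higher and 1 lower with KO mast cells, and 3 of them had an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 840 genes, where chance alone gives 877. The collagenase gene Mmp13 (chromosome 8 in the files) rose from 17.9 ± 0.572 CPM with WT to 24.5 ± 1.36 CPM with KO mast cells (SD, n = 3), a log2 fold change of 0.45 ± 0.055 (SE; edgeR adjusted p = 0.0243). Mrc1, the macrophage mannose receptor, fell from 48.3 ± 3.15 to 35.5 ± 2.3 CPM (-0.45 ± 0.057; edgeR adjusted p = 0.0287). Both mast cell protease genes rose, Cma1 from 2.82 ± 0.513 to 6.1 ± 0.738 CPM (1.11 ± 0.13; edgeR adjusted p = 0.0232) and Cpa3 from 2.35 ± 0.33 to 4.42 ± 0.303 CPM (0.91 ± 0.11; edgeR adjusted p = 0.0243). Tcea1l1, a gene related to the transcription elongation factor gene Tcea1, rose from 5.23 ± 0.343 to 10.2 ± 1.18 CPM (0.97 ± 0.09; edgeR adjusted p = 0.00364). Tcea1 itself was at 66.5 ± 0.242 and 57.8 ± 3.73 CPM (edgeR adjusted p = 0.473), and since the related genes can share reads, the split between them is uncertain. The remaining 2 called genes, named after their values were seen, were low. Libraries can agree closely by chance at such levels, so the SDs and SEs of these genes may be too small. Cd28, the costimulatory receptor of T cells, rose from 0.285 ± 0.00384 to 1.13 ± 0.035 CPM (1.99 ± 0.15; edgeR adjusted p = 8.29e-04), and the lncRNA gene ENSRNOG00000070496 from 0.121 ± 0.00708 to 1.47 ± 0.354 CPM (3.59 ± 0.23; edgeR adjusted p = 2.74e-04).

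**Figure D1:**
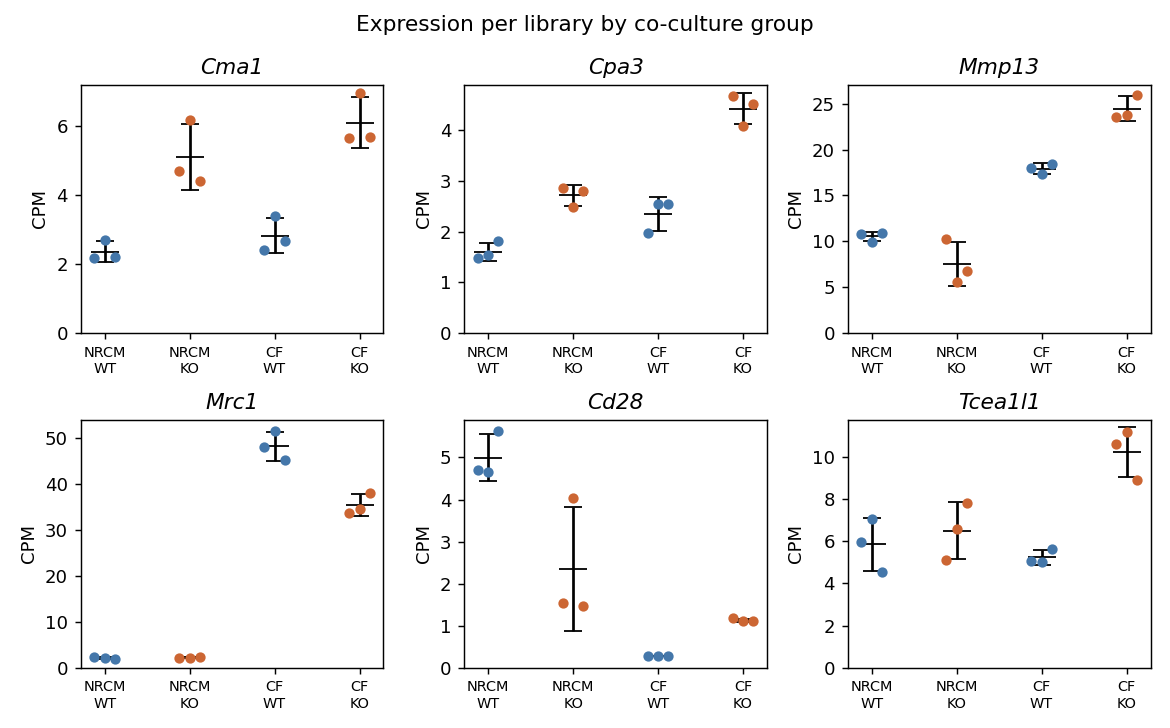
CPM per library (points), with the group mean and SD (bars, n = 3), of the 6 called CF genes that have a symbol, in NRCM and CF cultured with WT (blue) or KO (orange) mast cells. In CF, Cd28 stood at 0.285 ± 0.00384 CPM with WT and 1.13 ± 0.035 CPM with KO mast cells, and for Cd28 in NRCM the KO library nearest to the WT libraries was replicate 2.

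The coordinates name no genome build, and their contig names look like those of a later rat assembly than the one in the processing notes, so the build of these positions is uncertain. In them, Tcea1l1 lies at 10400829 to 10402942 on chromosome 15, Cd28 at 62166192 to 62191787 on chromosome 9 and ENSRNOG00000070496 at 29896072 to 29913623 on chromosome 4; Tcea1l1 and Cd28 are annotated as protein-coding. Tcea1l1, Cd28 and ENSRNOG00000070496 passed in each of the 6 edgeR fits that left out a library. Mmp13 and Mrc1 each passed in 1 of those 6, without KO replicate 3, and did not without any of the others (edgeR adjusted p of 0.0303 to 0.29 and 0.0206 to 0.24). Cma1 passed in 2, without WT replicate 2 and without KO replicate 3 (0.00703 to 0.152), and Cpa3 in 2, without WT replicate 1 and without KO replicate 2 (0.0461 to 0.172). With a block for replicate number, whose pairing of the libraries is uncertain, edgeR called 4 genes. ENSRNOG00000070496, Cd28 and Cma1 kept their calls and ENSRNOG00000062895 gained 1. Tcea1l1 (edgeR adjusted p = 0.0664), Mmp13 (0.0861), Cpa3 (0.219) and Mrc1 (0.267) lost theirs. Over all alternatives their adjusted p ranged from 3.07e-22 to 0.177, 1.96e-11 to 1, 1.48e-10 to 0.231 and 5.01e-11 to 1 in that order. Over the same 18 alternatives the adjusted p of ENSRNOG00000070496 ranged from 6.9e-32 to 0.0231, past the threshold in all 18, that of Cd28 from 1.78e-14 to 0.177, past it in 16, and that of Cma1 from 6.15e-15 to 0.285, past it in 11. Without KO replicate 1, edgeR called 3 genes in CF; in a single edgeR fit of all 4 groups it called 1, ENSRNOG00000070496, with Cd28 and Tcea1l1 at an adjusted p of 0.177 and Cma1 at 0.0742, and DESeq2 called 39, 19 higher and 20 lower.

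The inflammatory cytokine and NF-kB target list was called higher in CF: 27 of 33 members had a higher mean with KO mast cells, the median log2 fold change was 0.077 (1.06-fold), and camera gave an adjusted p of 2.09e-07. With an estimated correlation the camera adjusted p = 0.0675, and fry gave an adjusted p of 0.00925; over its 14 alternatives the adjusted p ranged from 1.02e-07 to 0.0675. Of its members, 6 passed adjusted over the list alone, all higher, and 0 over all genes tested. Nos2 was at 296 ± 7.42 CPM with WT and 333.7 ± 8.46 CPM with KO mast cells (SD, n = 3), a log2 fold change of 0.17 ± 0.035 (SE). The neutrophil chemokine genes Cxcl2 and Cxcl3 had log2 fold changes of 0.18 ± 0.04 and 0.14 ± 0.036, and Ptgs2, the inducible cyclooxygenase, 0.17 ± 0.043. The complement gene C3 lay on the other side, at 1308 ± 30.2 and 1191 ± 71.1 CPM (-0.13 ± 0.051).

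Macrophage markers were called lower in CF, where 16 of 18 members had a lower mean with KO mast cells, the median log2 fold change was -0.15 and camera gave an adjusted p of 5.04e-07. With an estimated correlation the camera adjusted p = 0.531, the largest over its alternatives (from 4.88e-10). Of the members, 4 passed adjusted over the list alone, all lower, and Mrc1 also passed over all genes tested. Lyz2, which encodes lysozyme, was at 422.9 ± 22.5 CPM with WT and 331.8 ± 16.6 CPM with KO mast cells (SD, n = 3; -0.35 ± 0.049; edgeR adjusted p = 0.0565). The lysosomal protease gene Ctss was at 26.5 ± 1.95 and 22 ± 1.32 CPM (-0.27 ± 0.064) and Cd68 at 57.1 ± 2.94 and 51.7 ± 1.27 CPM (-0.14 ± 0.041). Adgre1, which encodes the F4/80 antigen, had a log2 fold change of 0.0037 ± 0.045, and Cd14, the lipopolysaccharide co-receptor, -0.027 ± 0.028.

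**Figure D2:**
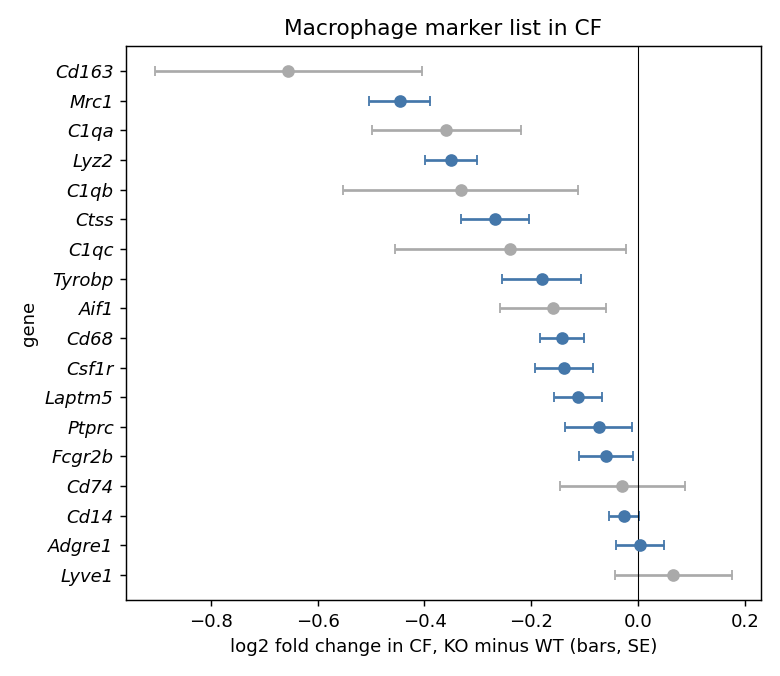
Log2 fold change (x axis, KO minus WT; bars, SE) of the 18 tested macrophage markers in CF, from edgeR fits with 3 libraries per group; grey points mark genes under 10 CPM in both groups. Mrc1 (-0.45) and Lyz2 (-0.35) lie apart from Cd14 (-0.027) and Adgre1 (0.0037).

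In CF, 3 more lists were called by camera, none of them with an estimated correlation. The estimated correlations were 0.814 for sarcomere, 0.594 for cell cycle and 0.085 for immediate early genes, against the preset 0.01. The p from the preset is therefore too small for these lists. Sarcomere genes were higher (26 of 28 above 0, median 0.097, adjusted p = 0.00454; adjusted p = 0.883 with an estimated correlation, 4.05e-06 to 0.925 over all alternatives), with Mybpc3, cardiac myosin-binding protein C, at 269.9 ± 19.4 and 306.1 ± 30.6 CPM and Actn2 at 294.8 ± 8.14 and 316.6 ± 13.4 CPM (SD, n = 3). Cell cycle genes were lower (26 of 33 below 0, median -0.063, camera adjusted p = 0.00644; adjusted p = 0.883 with an estimated correlation, 6.97e-09 to 0.886 over all alternatives), with Kif23 and Nusap1, genes of the mitotic spindle, at log2 fold changes of -0.17 ± 0.064 and -0.18 ± 0.069. Immediate early genes were higher (17 of 23 above 0, median 0.054, camera adjusted p = 0.0088; adjusted p = 0.537 with an estimated correlation, 0.0018 to 0.537 over all alternatives), with the transcription factor genes Nr4a1 at 0.28 ± 0.075 and Egr1 at 0.21 ± 0.062. In these 3 lists 0 members passed adjusted over the list alone. Whether the share of cardiomyocytes in the CF cultures differed was not tested. The sarcomere call was lost without WT replicate 3 (median 0.036, camera adjusted p = 0.237) and without KO replicate 3, where the median was -0.0079 (0.925); without KO replicate 2 the median was 0.15. The cell cycle call was lost without WT replicate 3 (median -0.04, 0.187), KO replicate 1 (0.122) or KO replicate 2 (-0.021, 0.33), and its median was -0.098 without KO replicate 3. The immediate early call was lost without WT replicate 3 (median 0.031, 0.0967) or KO replicate 1 (0.0593). Without KO replicate 2, camera called 10 lists in CF in place of 5.

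Among matrix and fibroblast genes in CF, Col1a1 was at 8742 ± 363 CPM with WT and 8810 ± 163 CPM with KO mast cells (SD, n = 3; log2 fold change 0.011 ± 0.062), and Col3a1 (-0.06 ± 0.049), Acta2 (0.014 ± 0.045), Postn (0.0087 ± 0.052), Fn1 (0.027 ± 0.071) and Ccn2 (-0.014 ± 0.041) likewise differed by less than 2 SE. Camera's adjusted p, given here in brackets, was over 0.05 for 20 lists in CF. The median log2 fold change was -0.026 for extracellular matrix genes (0.0648), 0.0042 for myofibroblast and TGF-beta genes (camera's direction down, 0.98), 0.036 for matrix proteases and inhibitors (0.0615) and -0.031 for fibroblast identity genes (0.0648). Mmp13 passed adjusted over the list alone among the proteases and Itga11, an integrin that binds collagen, among the myofibroblast genes, at 24.9 ± 0.443 and 21.6 ± 0.833 CPM (-0.21 ± 0.047). The interferon response had a median of -0.037 (0.116), with Mx2 at -0.42 ± 0.11 and Bst2 at 0.16 ± 0.056. The median was 0.046 for fetal and hypertrophic genes (0.22), 0.051 for calcium handling (0.0615), 0.0066 for fatty acid oxidation (mean -0.0083, 0.754), 0.029 for oxidative phosphorylation (0.245), -0.017 for glycolysis and hypoxia (0.498), -0.029 for the unfolded protein response (0.498), 0.045 for cholesterol synthesis (0.263) and 0.045 for p53 targets (0.0881). Plk2, a p53 target that encodes a polo-like kinase, passed over its list alone (0.18 ± 0.039), as did Ddit3 of the unfolded protein response (0.19 ± 0.047) and Gdf15 of the fetal list (0.39 ± 0.11). NRF2 genes had a median of 1.23e-05 (camera's direction down, 0.869) and ganglioside metabolism genes -0.026 (0.175), with Ugcg, the glucosylceramide synthase, at -0.11 ± 0.037. For other cell types the median was 0.033 for mast cell (0.0648), 0.015 for endothelial (0.498), -0.053 for mural (0.727), 0.0081 for epicardial (mean -0.0069, 0.98) and 0.34 for erythroid markers (0.116). Cma1 and Cpa3 passed among the mast cell markers, adjusted over the list alone and over all genes. Single libraries decided several of these results. Without KO replicate 2, fetal (0.0243), calcium handling (0.00586), matrix (0.0387), interferon (0.00346), p53 (0.0387) lists passed, as did the CF list mast cell markers (0.0498). Without WT replicate 3 the matrix (0.0494), glycolysis (0.00927), cholesterol (0.0019) and mast cell lists (0.0257) passed. Cholesterol (0.00149) and protease lists (0.0018) passed without KO replicate 3. The CF list calcium handling and ion channels (0.0156) and oxidative phosphorylation (0.0412) passed without KO replicate 1, calcium handling (0.0323) without WT replicate 1 and erythroid markers (0.0357) without WT replicate 2.

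The third comparison asked whether the effect of the mast cell genotype differed between the cardiac cell types. Genes that were lower with KO mast cells in NRCM and higher in CF at an unadjusted p under 0.05 numbered 16 of 16936, where independent lists give 5.59 (two-sided Fisher's exact test, p = 1.66e-04); genes are not independent, so this p is too small. They included Csf2, Csf3, Cxcl2, Cxcl3, Nos2, Ptgs2, Mmp3, Mmp9, Mmp13 and Cd28, and this count was chosen after the data were seen. It was 36 without NRCM KO replicate 2, 8 without NRCM WT replicate 1 and 9 without NRCM WT replicate 3. The number for independent lists was not computed for these fits, so they show only how far the count moved. In the opposite arrangement, higher in NRCM and lower in CF, there were 3 genes against 4.13 for independent lists (two-sided Fisher's exact test, p = 0.802). Cd28 itself stood at 5 ± 0.548 CPM in NRCM with WT and 2.35 ± 1.46 CPM with KO mast cells (SD, n = 3), a log2 fold change of -1.09 ± 0.36 (SE) that did not pass in edgeR. In edgeR's test of the difference, Nos2 had a log2 difference (CF minus NRCM) of 0.46 ± 0.082 (SE; edgeR adjusted p = 0.201), Mmp9 0.52 ± 0.095 (0.201), Csf3 0.74 ± 0.16 (0.562), Zmynd15 0.56 ± 0.12 (0.562) and Cbx7 had 0.39 ± 0.09 (0.664). In the other direction stood Mrc1 with -0.53 ± 0.12 (0.562), the growth factor gene Igf1 with -0.47 ± 0.12 (0.957), Atrx with -0.22 ± 0.059 (0.963), Fem1c with -0.23 ± 0.069 and Fxyd2 with -0.36 ± 0.12 (both 1). Cma1 and Cpa3 had differences of 0.0084 ± 0.23 and 0.16 ± 0.18. Of 18458 genes tested, edgeR called 0; 678 had an unadjusted p under 0.05, where chance gives 923, and DESeq2 called 18, 15 of them with a larger log2 fold change in CF. The smallest edgeR adjusted p was 0.0662, shared by ENSRNOG00000070496, ENSRNOG00000062648, Cd28 and ENSRNOG00000065366. Without NRCM KO replicate 2, edgeR called 6 genes, Cd28, Nos2 and Csf3 among them, without NRCM KO replicate 1 it called 3, and without NRCM WT replicate 1 or CF WT replicate 3 it called 1.

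**Figure D3:**
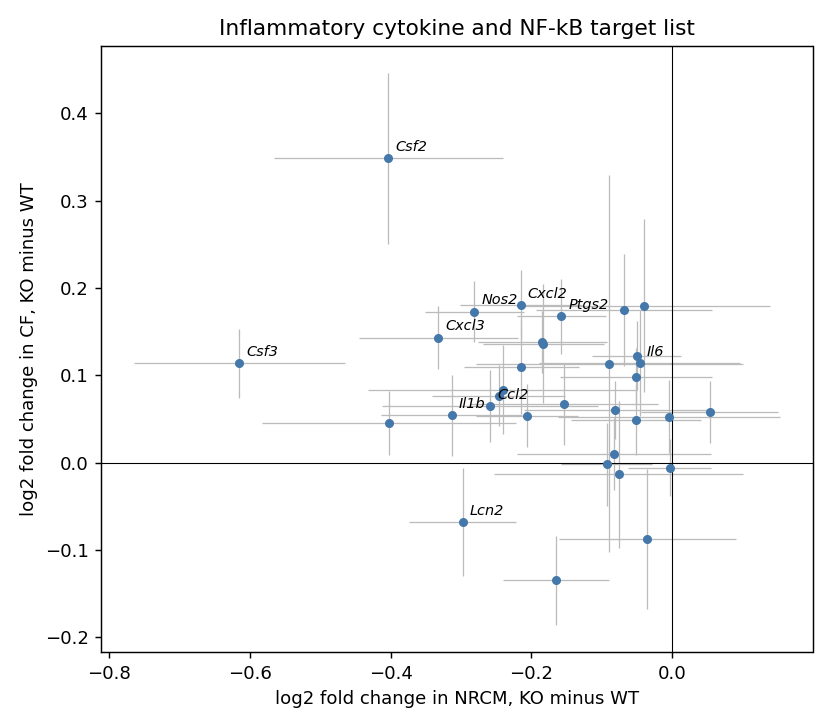
Log2 fold change, KO minus WT, of the 33 inflammatory list members in NRCM (x axis) and CF (y axis), with SE bars from edgeR fits of 3 libraries per group. Of the 33, 32 lie left of 0 in NRCM and 27 lie above 0 in CF.

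Over all 16936 genes tested in both cell types, the log2 fold changes had a Pearson r of 0.0304 and a Spearman rho of 0.0859 across genes, which are not independent replicates. Over the 8830 genes at 10 CPM or more in both cell types, r was 0.095 and rho 0.122. Over all genes tested in both, leaving out single libraries moved Pearson's r between -0.053 and 0.055, and r was below 0 without NRCM KO replicate 2 or 3, CF WT replicate 3 or CF KO replicate 3. At an unadjusted p under 0.05, 16 genes were lower in both cell types (6.23 for independent lists; two-sided Fisher's exact test, p = 5.55e-04), among them the cytokine signalling inhibitor gene Socs1 and the oncostatin M receptor gene Osmr. This count was 34 without NRCM KO replicate 2, 27 without CF KO replicate 3 and 10 without CF WT replicate 2. For fits without a library, the number for independent lists was again not computed. Likewise, 7 were higher in both (3.71 for independent lists; two-sided Fisher's exact test, p = 0.102), Cma1 and Cpa3 among them, and between 3 and 14 when single NRCM libraries were left out. No gene passed edgeR's adjusted threshold in both cell types (0 of 16936), which was fixed by the 0 calls in NRCM. DESeq2 called 2 in both with the same direction, the mast cell protease genes Cma1 and Cpa3.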

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

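The tests of lists on the difference of effects, the count of macrophage markers off a common shift, the macrophage test of the CF rise, the tests of library scaling, the comparison of the smallest p over all lists between splits, the test of the other mast cell genes, and the tests of whether a single library carries the rise of Cma1 and Cpa3 or the NRCM fall were chosen after the results were seen.

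The effect of the mast cell genotype on 6 lists differed between cell types in camera's test of the difference (CF minus NRCM). The inflammatory list had a median log2 difference of 0.24 (adjusted p = 5.41e-15; adjusted p = 3.25e-04 with an estimated correlation, the largest of its 16 alternatives, from 1.81e-17). Glycolysis and hypoxia genes had -0.091 (adjusted p = 3.75e-05; 0.534 with an estimated correlation), macrophage markers -0.15 (0.00785; 0.214), extracellular matrix genes -0.072 (0.00982; 0.95), matrix proteases 0.049 (0.0142; 0.214) and unfolded protein response genes -0.083 (0.0213; 0.95). Over all alternatives the adjusted p of these 5 lists ranged from 2.5e-07 to 0.534, 5.11e-04 to 0.214, 1.26e-04 to 0.95, 0.0052 to 0.214 and 9.27e-04 to 0.95 in that order. The matrix call was lost without NRCM WT replicate 2 (0.255) and without NRCM KO replicate 2 (median 0.015, 0.712), and its median was -0.11 without NRCM WT replicate 1 or NRCM KO replicate 1. The protease call was lost without NRCM KO replicate 3 (0.0712) or CF KO replicate 2 (0.0549), and its median was 0.12 without NRCM WT replicate 2, 0.074 without NRCM KO replicate 2, 0.027 without CF KO replicate 1 and 0.081 without CF KO replicate 3. The glycolysis median was -0.044 without NRCM KO replicate 2 and -0.14 without NRCM KO replicate 1, and the macrophage median -0.23 without NRCM KO replicate 1. The unfolded protein response call was lost without WT replicate 2 (median -0.042, 0.277), WT replicate 3 (0.0567) or KO replicate 2 (-0.049, 0.309) of NRCM, or WT replicate 2 (0.0516), WT replicate 3 (0.113) or KO replicate 3 (0.151) of CF. Lists gained a call without NRCM KO replicate 2 (interferon response 4.15e-05, cell cycle 9.39e-09, immediate early 8e-07), NRCM WT replicate 1 (difference list cell cycle, 0.0124) and NRCM KO replicate 1 (difference list oxidative phosphorylation, 0.00173). In CF, leaving out WT replicate 2 added the difference list cholesterol synthesis (9.12e-04), immediate early genes (0.0455) and erythroid markers (0.0336), KO replicate 1 cholesterol synthesis (1.62e-04), WT replicate 3 oxidative phosphorylation (0.0118) and KO replicate 3 oxidative phosphorylation (0.0117) and immediate early genes (0.0472). As many lists or more were called in 64 of 100 drawn splits of the libraries, with 16 as the highest number beside the real 6, so chance is not excluded for the number of lists.

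The inflammatory list was called lower in NRCM and higher in CF with KO mast cells. With an estimated correlation the CF call was lost (camera adjusted p = 0.0675, range 1.02e-07 to 0.0675). The estimated correlation was -0.0101 in CF and -0.016 in NRCM, below the preset 0.01. Correlation between members therefore does not account for the loss. In NRCM the mast cell call was likewise lost at an estimated correlation of 0.0161, close to the preset. A call lost with an estimated correlation is thus not by itself a sign of correlated members. The difference of this list was singled out for having the smallest p of the 25 lists. In 16 of 100 drawn splits, the real split included, the smallest camera p over all lists was as small (minus log10 p of 15.7 in the real split and at most 24.8 in the others), so chance is not excluded for a list picked in this way. For this list alone the real split gave an absolute median difference of 0.239 and the highest of the others was 0.215 (1 of 100 as large, the real split included). The NRCM library that stands apart does not carry the fall, since the median was -0.187 without it. A scale factor common to all genes of a library cancels in a list's median relative to all genes. This score differed between KO and WT libraries by 0.0746 ± 0.00707 in CF and -0.17 ± 0.0225 in NRCM (SE, n = 3 libraries per group). With a median log2 fold change over all genes of -0.000576 in CF and 0.00352 in NRCM, it largely restates the list medians. It thus speaks only against a common factor, and is no independent support for the pattern. A bias that depends on expression level would not cancel. A larger share of macrophages in CF would raise the macrophage list, whose median was -0.151. These values do not cover a change in macrophage state, which was not tested. A response of the cardiac cells that depends on cell type and mast cell genotype may account for the pattern. It is a hypothesis found and tested on the same data. Chance, differences in culture handling between groups and a changed mix or state of the cells in the cultures stay open. Single genes did not pass edgeR's test of the difference.

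Cma1 and Cpa3 were higher with KO mast cells in both cell types. No single library carries this, since their lowest log2 fold change over all fits without a library was 0.7. More mast cell RNA left after washing could raise them. The other mast cell genes at 1 CPM or more had a median log2 fold change of 0.0254. Several of these, however, such as Kit and Il1rl1, were more abundant than Cma1 in NRCM, and Fcer1a and Ms4a2 had 0 counts. Below 1 CPM in NRCM, Tpsab1 had 15, 5 and 11 counts with WT and 20, 14 and 14 with KO mast cells. Mcpt10 had 8, 24 and 6 against 6, 0 and 12. In CF, Tpsab1 had 0, 0 and 7 against 13, 6 and 8, and Mcpt10 had 0 in each library. Leftover RNA and a change in the expression of Cma1 and Cpa3 therefore cannot be told apart. Whether the reads are of mouse or rat origin was not tested.

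Macrophage markers were called lower in CF with KO mast cells, but not with an estimated correlation (camera adjusted p = 0.531) or by fry (0.208), over a range of 4.88e-10 to 0.531. Relative to all genes the list's score differed by -0.139 ± 0.0483 (SE, n = 3 libraries per group), and a factor common to all genes of a library adds nothing to this score. At -2.88 SE from 0 it missed the 3 SE set for the test, with WT replicate 3, at -0.00189, near the KO libraries, so whether the score departs from 0 beyond the spread between libraries is open. The markers did not all fall by 1 amount. Mrc1, Lyz2 and Cd14, 3 of 11 at 10 CPM or more, lay over 3 SE from their common shift of -0.13. That shift was estimated from the same markers. Unequal falls cannot decide on fewer macrophages, since a marker also made by other cells would fall less. Fewer macrophages and a change in the state or the kind of macrophage present both stay open, and the latter was not tested.

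The splits of the 6 libraries of a cell type number 10, too few for a share under 0.05. In CF the real split gave 7 genes and the highest other 6, in NRCM 0 genes and 3. For lists the real split gave 5 in CF, with 12 as the highest other, and 6 in NRCM, with 11. As many lists or more came from 8 of the 10 splits in CF and 5 of 10 in NRCM, the real split included. Chance is therefore not excluded for the number of lists called in either cell type. For genes whose effect differs between cell types, the real count was 0, which each of the 100 drawn splits reaches by construction, so this comparison decides nothing; the highest count of the others was 4. An absolute Pearson r of 0.0304 between the cell types' effects or a larger value came from 41 of 100 pairs of splits, with 0.0894 as the highest other, so chance is not excluded for the correlation.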

How the results depend on the processing

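The settings of counts divided by 4, shared identifiers kept apart, RLE for lists and every test of lists on the difference were chosen after seeing the data; unless the construction shows it, the cause was not tested. NRCM called 14 genes with DESeq2, 3 with limma-voom, 3 with all 4 groups in a single fit, 1 with shared identifiers kept apart, and 0 to 1 without a library. CF called 39 with DESeq2, 14 with limma-voom, 4 (all higher) with the replicate block, 1 with all 4 groups in a single fit, 3 against a fold of 1.2, a stricter hypothesis, and 3 to 10 without a library; the 7 genes were all called by DESeq2, limma-voom and with counts divided by 4 (8 calls). The difference of effects gave 18 genes with DESeq2, 3 with no filter and 0 to 6 without a library. Lists called in NRCM numbered 1 with an estimated correlation, 1 with fry and 4 to 13 without a library; in CF 0, 1 and 5 to 10; for the difference 1 with an estimated correlation and 4 to 8 without a library. Pearson's r was 0.0649 with a filter of 1 CPM, and -0.0531 to 0.0548 without a library. DESeq2 called 2 genes in both cell types, Cma1 and Cpa3. Without a library the medians ranged, in NRCM, from -0.0235 to 0.108 for extracellular matrix, -0.0974 to 0.0741 for interferon, -0.15 to 0.135 for cell cycle, -0.037 to 0.111 for fatty acid oxidation and -0.04 to 0.0595 for NRF2 genes, from -0.114 to 0.0146 for the difference in extracellular matrix, and from -0.00791 to 0.147 for CF sarcomere genes; the ends of opposite sign came without NRCM KO replicate 2 and, for sarcomere genes, CF KO replicate 3. Of 3432 values of single genes, 37 lost and 43 gained a call and 0 called ones changed sign; of 1099 values of lists, 48 lost and 43 gained a call and 7 changed sign. Values past the threshold in neither setting were compared by that side only, and 43 of genes and 95 of lists changed sign. Whether the replicate numbers pair the libraries is uncertain. Deviations of same-numbered libraries correlated at -0.0703 to 0.267 in NRCM and -0.0589 to 0.158 in CF. Those of differently numbered libraries correlated at -0.388 to 0.0791 in NRCM and -0.168 to 0.105 in CF. The block changed the lists called in NRCM from 6 to 4, ending the matrix and oxidative phosphorylation calls. It left NRCM genes at 0, CF lists at 5 and genes of the difference at 0. Leaving out the KO libraries with a conflicting label left 1 KO library, assumed to vary like the WT libraries, and gave 0 genes in NRCM and 6 in CF, 2 of them among the 7. Depth limits genes near the floor of 3 counts, 0.0141 to 0.0227 CPM.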
